A study of Synechocystis sp. PCC 6803 with 6 samples.

How the data were processed

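RNA was measured in 6 cultures of the cyanobacterium Synechocystis, 3 of the glucose-tolerant wild type (GT) and 3 of a strain that overexpresses rre37. Per the labels' protocols, cells grew with 5 mM ammonium chloride as the nitrogen source under 50 to 70 micromol photons per square metre and second, RNA was isolated with hot phenol, and labelled cDNA was made with a commercial kit (version 2.0) and hybridised to the CyanoChip, a spotted microarray of this organism's genes. The GT samples carried the dye Cy3 and the overexpression samples Cy5, per the labels. No sample carried the other dye, so the fitted models attribute to the strain any dye effect on a gene's probe.

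The authors deposited 1 file per sample with the linear intensity of 2 spots for each of 3074 genes. The scanner, its software and any background treatment are not given in the sources used here. No intensity lay at or below 0, and the lowest was 137.5, so a background pedestal was taken to remain in the values. The files hold no background column, no flags and no control spots. The authors' table for the whole series holds intensities on a linear scale. It was recomputed to within 0.024% by dividing each set of spots by its own mean, multiplying by 1 constant and averaging the 2 spots, so its 6 columns share a mean of 3253, while their medians run from 2024 to 2594. It served as an alternative source of values.

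Intensities were corrected with the normexp model of limma 3.58.1 in R 4.3.3, fitted to the foreground of each sample with an offset of 50, and quantile-normalised over the 6 samples on the log2 scale. The 2 spots of a gene were averaged. The offset and any remaining pedestal make differences of dim genes smaller. Strains were compared gene by gene with limma's linear model and moderated test (two-sided), with Benjamini-Hochberg adjustment over all 3074 genes and a threshold of 0.05. A positive log2 difference is higher in the overexpression strain. Precision is limited by the number of samples, 3 per strain, and p-values cover only the spread between these samples. The design text calls the strains independent.

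The fit fixed in advance had no pairing. Same-numbered samples were then found to be paired. Over all genes, their deviations from the strain means correlated at r = 0.449 to 0.663, against -0.489 to -0.127 for other numbers. Deviations cancel out within a strain, so the negative values follow from the positive ones and add no evidence. The difference between the 2 spots of a gene also correlated between same-numbered samples (r = 0.456 to 0.715), against -0.0826 to 0.106 for every other pair of samples. A shared spot-by-spot pattern is what the 2 dyes of 1 slide give, although the labels do not say which samples shared a slide. The fit with the replicate number as a block, called the paired fit below, is therefore reported as well. Of the 260 genes that passed only with the block, only some members of the gene lists described below are named. A fit without pairing that leaves out 1 sample keeps its same-numbered partner, so what that pair shares enters the strain difference. Without 1 of the pairs the paired fit has 1 residual degree of freedom. The spread is then shared almost wholly between genes (prior degrees of freedom 1040 or unlimited, against 12.9 with all 3 pairs). This can make its p-values too small, which was not tested.

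Before the data were examined, 23 lists of genes were fixed by locus tag (290 genes, of which 288 were measured), with the alternatives and the rule for naming genes. Lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 23 lists), which asks whether a list's genes differ from the other genes. Genes of a shared operon differed alike (described below), so the preset correlation counts them as more independent than they are. The named genes are rre37, the up to 12 largest differences each way among genes past the threshold whose strains did not overlap, the 4 members of each list with the lowest p, and 3 loci often used as insertion sites. The files do not pair locus tags with names, and none of the 3074 tags matched the reference table used here, which has 3347 entries under other tags. Symbols are those set down with the fixed lists from general knowledge. Of called genes outside these lists, only 2 higher and 2 lower are given by tag. The 5 neighbours on each side of rre37, also planned, were not analysed here, because gene order was not available under these tags. In the arginine list, slr1077 had been entered where sll1077 was meant. The list was kept as fixed, and the corrected list is an alternative.

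The steps were tested on simulated intensities for the 3074 genes with genes changed by known sizes and the pairing of the real samples. Without the block, 69.0% of 100 genes changed by 2 on the log2 scale and 2.02% of 99 genes changed by 1 were recovered. With the block, 96.0% and 66.7% were recovered, and 4.65% of its calls were false. The simulated noise was normal, with each gene's spread taken from the paired fit to the real data. The test assumes such noise, so a false share near its threshold was largely set in advance. The simulation held no dye effect and no spot pattern shared within a pair. Its false share therefore does not cover dye effects among the real calls. Alternatives covered the background correction, the offset, median scaling, cyclic loess, loess within same-numbered pairs, a filter on dim genes, the prior of the test, the series table, other set tests, and leaving out samples. Figures were drawn with matplotlib 3.10.9.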

Results

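Transcript levels of 3074 genes were measured on a spotted microarray in 3 cultures of glucose-tolerant Synechocystis (GT) and 3 cultures of a strain overexpressing rre37, which encodes a response regulator. Cells of both strains were in log phase with ammonium as the nitrogen source, and the comparison asks which transcripts differ when this regulator is in excess. Median spot intensity was 296, 1044 and 626 in GT replicates 1, 2 and 3, and 849, 1192 and 1406 in overexpression replicates 1, 2 and 3. The 2 spots of a gene correlated within a sample at r = 0.774 to 0.914 (log2 intensity, across genes, which are not independent replicates).

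The rre37 gene (sll1330) was 33.8-fold higher in the overexpression strain (95% interval 21.8 to 52.2). Its normalised level was 8.92 ± 0.365 in GT and 14.0 ± 0.236 in the overexpression strain (log2 intensity, SD, n = 3 each). This was a log2 difference of 5.08 (SE 0.285), with a limma adjusted p of 6.79e-06. The size depends on the background step, with 17.6-fold without background correction and 16.8-fold in the series table, both past the threshold and both below that interval. Before normalisation, the mean of its 2 spots was 447, 1108 and 741 in the GT replicates and 16058, 24055 and 24036 in the overexpression replicates. The labels and the level of the overexpressed gene therefore matched in every sample.

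Of the 3074 genes, 25 differed between the strains at a limma adjusted p under 0.05, 18 of them higher and 7 lower in the overexpression strain. All 25 differed by at least 2-fold and in the same direction in all 3 same-numbered pairs. Without pairing, only 2.02% of simulated 2-fold changes were recovered, so these traits follow largely from the threshold. The strains did not overlap in any of the 25, nor in 18.6% of all genes. Chance gives 10% for exchangeable samples, and the other splits of the 6 samples gave 3.09% to 18.9%, those that part all 3 pairs 3.09% to 4.23%. Apart from rre37, the called genes with a place in the fixed lists were malQ, glgP, me, phaB, argJ, argD, carA and carB, all higher, and gifB and nrtB, both lower. The paired fit called 285 genes, 123 higher and 162 lower, and these included the same 25. The share of called genes that were higher was 72.0% without and 43.2% with the pairing. Of the 25 genes called without pairing, another 9 higher and 5 lower had no place in the lists. The largest of these were slr2031 (5.07-fold higher, adjusted p = 0.00642) and ssl2501 (4.69-fold higher, adjusted p = 0.0454), and sll1102 (3.09-fold lower, adjusted p = 0.0333) and slr2057 (3.03-fold lower, adjusted p = 0.0454). Leaving out GT replicate 3 or overexpression replicate 3 left 1 and 4 calls without pairing. The paired fit without each pair, whose p-values may be too small, gave 205 to 288. Of the genes named here, ssl2501, phaB and carA lost their call after median scaling, phaB and nrtB lost it in the series table, and ssl2501, sll1102, slr2057, phaB and carA lost it with an offset of 16. The call of ssl2501 was also lost with cyclic loess (adjusted p = 0.0645), and those of ssl2501 and phaB without the dimmest 25% of genes (0.0501 each). Folds were smaller where the background was left in. Of 22 called genes compared, 16 had a fold over 1.5 times smaller without background correction and 19 in the series table. Because each strain had its own dye, a dye effect on the probe of any 1 gene cannot be separated from a strain effect.

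**Figure D1:**
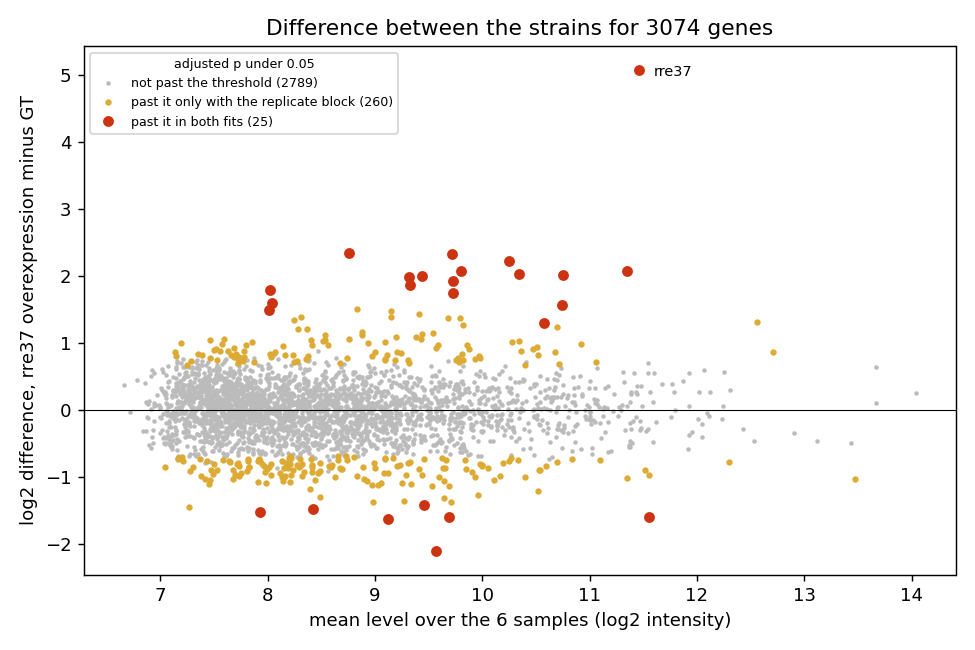
Log2 difference between the strains (rre37 overexpression minus GT, vertical axis) against the mean log2 intensity over the 6 samples (horizontal axis), 1 point per gene. The 25 red genes passed the threshold in both fits, the 260 yellow genes only with the replicate block, and rre37 stands apart at 5.08.

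Among the genes of carbon storage, malQ and glgP of glycogen breakdown and phaB of the synthesis of polyhydroxybutyrate, a storage polyester, rose in the overexpression strain. In the glycogen breakdown list, 2 of 5 genes rose. These were malQ (sll1676), a glucanotransferase gene, which was 5.03-fold higher (log2 difference 2.33, SE 0.336, adjusted p = 0.00892, but 2.81-fold both without background correction and in the series table), and the glycogen phosphorylase gene glgP (slr1367), 4.21-fold higher (log2 difference 2.07, SE 0.318, adjusted p = 0.0128). The second glycogen phosphorylase gene (sll1356) and the debranching enzyme gene glgX (slr0237) had log2 differences of -0.029 (SE 0.295) and -0.70 (SE 0.314), with adjusted p of 0.983 and 0.408. The mean of the list was 0.73 and its median -0.0034 on the log2 scale, and camera did not call it (adjusted p = 0.110, paired 0.105). It was called higher without overexpression replicate 1 (0.0360) and in the paired fit without pair 1, 2 or 3 (0.00121, 0.0456 and 0.00510). The fits without a pair have 1 residual degree of freedom, and their p-values may be too small. With an estimated correlation its adjusted p was 0.520 without pairing and 0.428 with all 3 pairs. Of its genes, adjusted over the list alone, 2 were higher in both fits and 1 was lower in the paired fit. Of the 4 polyhydroxybutyrate genes, all had positive differences. The acetoacetyl-CoA reductase gene phaB (slr1994) rose 3.37-fold (adjusted p = 0.0454), and was 2.16-fold higher without background correction and 2.19-fold in the series table (adjusted p = 0.107). The thiolase gene phaA (slr1993, 2.80-fold) and the polymerase subunit gene phaE (slr1829, 2.14-fold) passed only in the paired fit (adjusted p = 4.67e-04 and 0.00527). The polymerase subunit gene phaC (slr1830) was 1.40-fold higher and passed in neither fit (adjusted p = 0.505 and 0.142). Adjusted over the list alone, 3 of the 4 passed without pairing and 4 with it. Camera called the polyhydroxybutyrate list higher (adjusted p = 1.54e-04), with an adjusted p = 0.495 with an estimated correlation.

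In the glycolysis list, which also holds gluconeogenic enzymes, none of 18 genes passed without pairing (1 higher and 1 lower adjusted over the list alone, and 4 and 1 in the paired fit). In the paired fit 4 rose and 1 fell. The glyceraldehyde-3-phosphate dehydrogenase gene gap1 (slr0884) was 2.60-fold higher (paired adjusted p = 7.79e-04), the phosphofructokinase gene pfkA (sll1196) 2.41-fold higher (paired adjusted p = 0.00136), and the enolase gene eno (slr0752) 1.88-fold higher (paired adjusted p = 0.0123). The phosphoglycerate kinase gene pgk (slr0394) was 2.30-fold lower (paired adjusted p = 0.00327). The list was not called by camera (adjusted p = 0.220). The malic enzyme gene me (slr0721), in the list of pyruvate dehydrogenase and tricarboxylic acid cycle genes, rose 4.0-fold (adjusted p = 0.00744), and 2.19-fold without background correction and 2.16-fold in the series table. The other 15 of these 16 genes did not pass in either fit, among them icd (slr1289), isocitrate dehydrogenase, with a log2 difference of 0.72 (SE 0.328), and ppc (sll0920), with -0.43 (SE 0.256). None of 8 genes of the oxidative pentose phosphate pathway passed in either fit. Their median log2 difference was -0.25, with -0.44 (SE 0.301) for zwf (slr1843), -0.48 (SE 0.355) for gnd (sll0329) and -0.69 (SE 0.258) for pgl (sll1479). Of 6 glycogen synthesis genes, the branching enzyme gene glgB (sll0158) was 1.77-fold lower in the paired fit (adjusted p = 0.0219), and 5 did not pass. Camera called neither the tricarboxylic acid cycle (adjusted p = 0.198), the pentose phosphate (adjusted p = 0.271) nor the glycogen synthesis list (adjusted p = 0.271). In the series table it called the pentose phosphate (0.0373) and glycogen synthesis lists (0.0438) lower. Their means there were nearer to no difference, -0.14 and -0.19 against -0.20 and -0.26. The median of all genes was 0.12 in that table, against 0.0012, and camera compares a list with the other genes. Adjusted over the list alone, 1 gene of each of these 2 lists was lower and 2 of the tricarboxylic acid cycle list were higher in the paired fit, against 0, 0 and 1 without pairing.

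**Figure D2:**
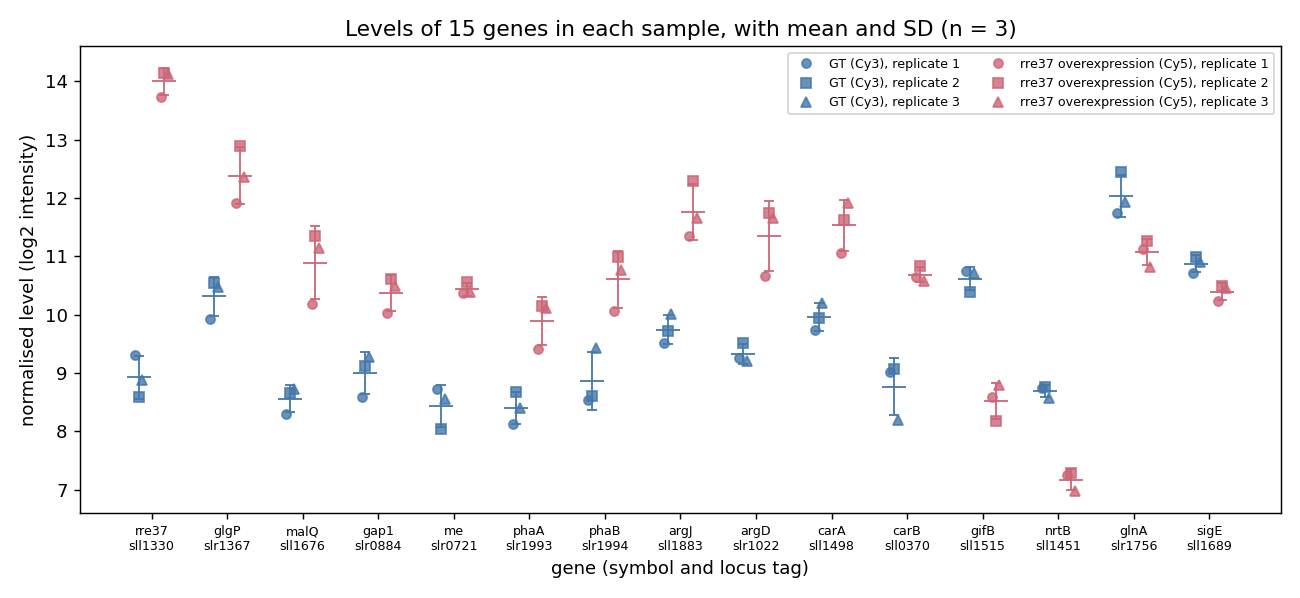
Normalised log2 intensity (vertical axis) of 15 genes in each sample, with the replicate number as the symbol, and the mean and SD (n = 3) of each strain as bars. The overexpression samples of rre37 lie at 13.7 to 14.1, above the GT samples at 8.58 to 9.31, and the levels of gifB and nrtB are lower in all 3 overexpression samples.

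Genes of ornithine synthesis and of carbamoyl phosphate synthase, both on the way to arginine, rose, while the nitrate transporter gene nrtB and gifB fell. Of 16 genes in the arginine, ornithine and cyanophycin list, 4 rose without pairing. These were argD (slr1022, 4.08-fold, adjusted p = 0.0158) and argJ (sll1883, 4.05-fold, adjusted p = 0.0128), both of ornithine synthesis, and the carbamoyl phosphate synthase genes carB (sll0370, 3.79-fold, adjusted p = 0.0137) and carA (sll1498, 2.98-fold, adjusted p = 0.0406). In the paired fit 6 rose and 1 fell. The one that fell was slr1077, the tag entered in error. Adjusted over the list alone, 5 were higher and 1 lower without pairing, and 6 and 2 with it. In the series table carB was 2.33-fold, argD 2.60-fold and argJ 2.66-fold higher. The list's mean log2 difference was 0.47 and its median 0.16. Camera called it higher (adjusted p = 0.0204), and adjusted p = 0.520 with an estimated correlation. Without overexpression replicate 2 its adjusted p was 0.0568, and with camera on ranks 0.248.

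Of 23 nitrogen assimilation genes, 2 fell without pairing. The gifB gene (sll1515), which encodes an inactivating factor of glutamine synthetase, was 4.28-fold lower (log2 difference -2.10, SE 0.273, adjusted p = 0.00733), and 2.44-fold lower both without background correction and in the series table. The nitrate transporter gene nrtB (sll1451) was 2.88-fold lower (log2 difference -1.52, SE 0.252, adjusted p = 0.0186). In the paired fit 2 genes rose and 6 fell. The glutamate synthase gene gltD (sll1027) was 2.36-fold higher (paired adjusted p = 0.00166), and the glutamine synthetase gene glnA (slr1756) 1.96-fold lower (paired adjusted p = 0.0118). The nrtA (sll1450), nrtC (sll1452) and nrtD (sll1453) genes, chosen after their values were seen, had log2 differences of -0.85, -0.75 and -0.82 (paired adjusted p = 0.0314, 0.0353 and 0.0275). Adjusted over the list alone, 1 was higher and 3 were lower without pairing, and 2 and 6 with it. Camera did not call the list (adjusted p = 0.131). In the series table the nrt genes of this operon, narB included, had a mean log2 difference of -0.20, against -0.81, and nrtB one of -0.43 (adjusted p = 0.425). Without background correction nrtB was 1.48-fold lower (adjusted p = 0.0461).

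In the photosynthesis lists no gene passed without pairing. In the paired fit, 2 of 12 photosystem I genes fell, psaA (slr1834, 2.04-fold, adjusted p = 0.0111) and psaF (sll0819, 1.86-fold, adjusted p = 0.0241), and 1 of 22 photosystem II genes, psbA1 (slr1181, 1.79-fold, adjusted p = 0.0212). Of 11 carbon fixation and carboxysome genes, the carboxysome genes ccmK1 (sll1029, 1.83-fold, adjusted p = 0.0176) and ccmN (sll1032, 1.73-fold, adjusted p = 0.0363) fell in the paired fit. Adjusted over the list alone, 2 photosystem I genes were lower without pairing, and no gene of the other photosynthesis and carbon uptake lists passed. With pairing these counts were 2 lower for photosystem I, 1 lower for photosystem II, 4 lower for carbon fixation, and 3 higher and 1 lower for the NDH-1 list, and 0 for the others. None of 15 phycobilisome, 9 ATP synthase and 11 chlorophyll synthesis genes passed in either fit. In the list of the NDH-1 complex, respiratory oxidase and cytochrome b6f, 2 of 18 genes rose in the paired fit, among them the oxidase subunit gene ctaD (slr1137, 1.72-fold, adjusted p = 0.0275). The phycobilisome list had a mean of -0.010 and a median of 0.013, and the NDH-1 list 0.023 and -0.072. The 10 genes of inorganic carbon uptake had a mean log2 difference of -0.35, and 1 of them was positive. Camera called this list lower (adjusted p = 0.0413, and adjusted p = 0.495 with an estimated correlation), although no member passed by itself. Its members included ndhF3 (sll1732), with a log2 difference of -0.61 (SE 0.247), and the bicarbonate transporter gene sbtA (slr1512), with -0.56 (SE 0.308). The call was lost without GT replicate 2 (adjusted p = 0.139), GT replicate 3 (0.0952) or overexpression replicate 1 (0.0568) or 2 (0.109). It was also lost with an offset of 16 (0.0501), in the series table (0.0783, mean -0.063), with the first spot alone (0.349), and in the paired fit without pair 2 (0.228) or 3 (0.0609). Camera did not call the photosystem I, photosystem II, carbon fixation, phycobilisome, ATP synthase, NDH-1 or chlorophyll lists (adjusted p = 0.220, 0.271, 0.271, 0.942, 0.942, 0.942 and 0.499). Photosystem I was called lower in the series table (0.0373, mean -0.17 against -0.23) and without overexpression replicate 1 (0.0360). Photosystem II was called lower without that sample (0.0360) or GT replicate 2 (0.0459), with means of -0.32 and -0.34. Its mean was 0.047 without GT replicate 1 and 0.045 without overexpression replicate 2. In the paired fit without pair 1, 2 or 3 it was -0.13, -0.15 and -0.15, with no call. Photosystem I then had -0.25, -0.23 and -0.20, also with no call. Carbon fixation was called lower in the series table (0.0155, mean -0.19 against -0.20), where the median of all genes was 0.12.

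The 14 genes of heat shock, chaperones and high-light-inducible proteins had a mean log2 difference of 0.34. Camera called the list higher (adjusted p = 0.0413, and adjusted p = 0.495 with an estimated correlation). No member passed without pairing. In the paired fit the chaperone gene dnaK2 (sll0170) was 1.96-fold higher (adjusted p = 0.00980) and the sigma factor gene sigB (sll0306) 1.83-fold higher (adjusted p = 0.0165). The list lost its call without GT replicate 2 (adjusted p = 0.139), GT replicate 3 (0.0952) or overexpression replicate 2 (0.0568). It was also lost with an offset of 16 (0.0501), in the series table (0.0783), with camera on ranks (0.0515), with the second spot alone (0.0894), and in the paired fit without pair 2 (0.205) or 3 (0.0518). The 29 ribosomal protein genes had a mean log2 difference of 0.24, and 23 were positive. Ribosomal genes of a shared operon (17 measured, 14 positive) are not independent of one another. The list was called in the paired fit (adjusted p = 0.0242, and adjusted p = 0.428 with an estimated correlation) but not without pairing (adjusted p = 0.0642), and 1 member, rpl6 (sll1810, 1.98-fold), passed in the paired fit (adjusted p = 0.0127). That paired call was lost without pair 1, 2 or 3 (adjusted p = 0.115, 0.0611 and 0.0518). Without pairing the list was called without GT replicate 1 (mean 0.41) or overexpression replicate 2 (0.36) or 3 (0.34). Without overexpression replicate 1 the mean was 0.026. The paired fit without pair 1, 2 or 3 gave means of 0.20, 0.26 and 0.26.

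Among 9 type IV pilus genes, pilO (slr1276, 2.03-fold lower, adjusted p = 0.00675) and pilM (slr1274, 1.90-fold lower, adjusted p = 0.0229) fell in the paired fit. Among 9 sigma factor genes, sigG (slr1545) was 1.71-fold lower in the paired fit (adjusted p = 0.0327). The sigE gene (sll1689), whose product controls sugar catabolic genes, had a log2 difference of -0.48. Its SE was 0.252 without pairing (adjusted p = 0.503) and 0.201 in the paired fit (adjusted p = 0.150). Of 12 phosphate uptake genes, the phosphatase gene phoA (sll0654) was 1.66-fold lower in the paired fit (adjusted p = 0.0407). Of 9 iron genes, the bacterioferritin gene with the tag slr1890 was 1.82-fold higher and the iron-binding protein gene futA2 (slr0513) 1.67-fold lower in the paired fit (adjusted p = 0.0242 and 0.0412). Adjusted over the list alone, 2 pilus genes were lower without pairing, and none of the stress, ribosomal, sigma factor, phosphate, iron or hydrogenase genes passed. With pairing these counts were 3 lower for the pilus, 4 higher for the stress list, 1 higher for the ribosome, 2 higher and 1 lower for the sigma factors, 1 lower for phosphate, 1 higher and 1 lower for iron, and 2 higher for the hydrogenase. Adjusted over all genes, none of 5 hydrogenase genes passed in either fit, with a log2 difference of 0.70 (SE 0.322) for hoxH (sll1226). Camera called none of these lists (adjusted p = 0.131 for the pilus, 0.673 for the sigma factors, 0.271 for phosphate, 0.779 for iron and 0.271 for the hydrogenase). The pilus list was called lower in the series table (0.00508, mean -0.27 against -0.33) and without GT replicate 1 (0.0437, mean -0.43). The paired fit without pair 1, 2 or 3 did not call it (means -0.31, -0.32 and -0.36).

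**Figure D3:**
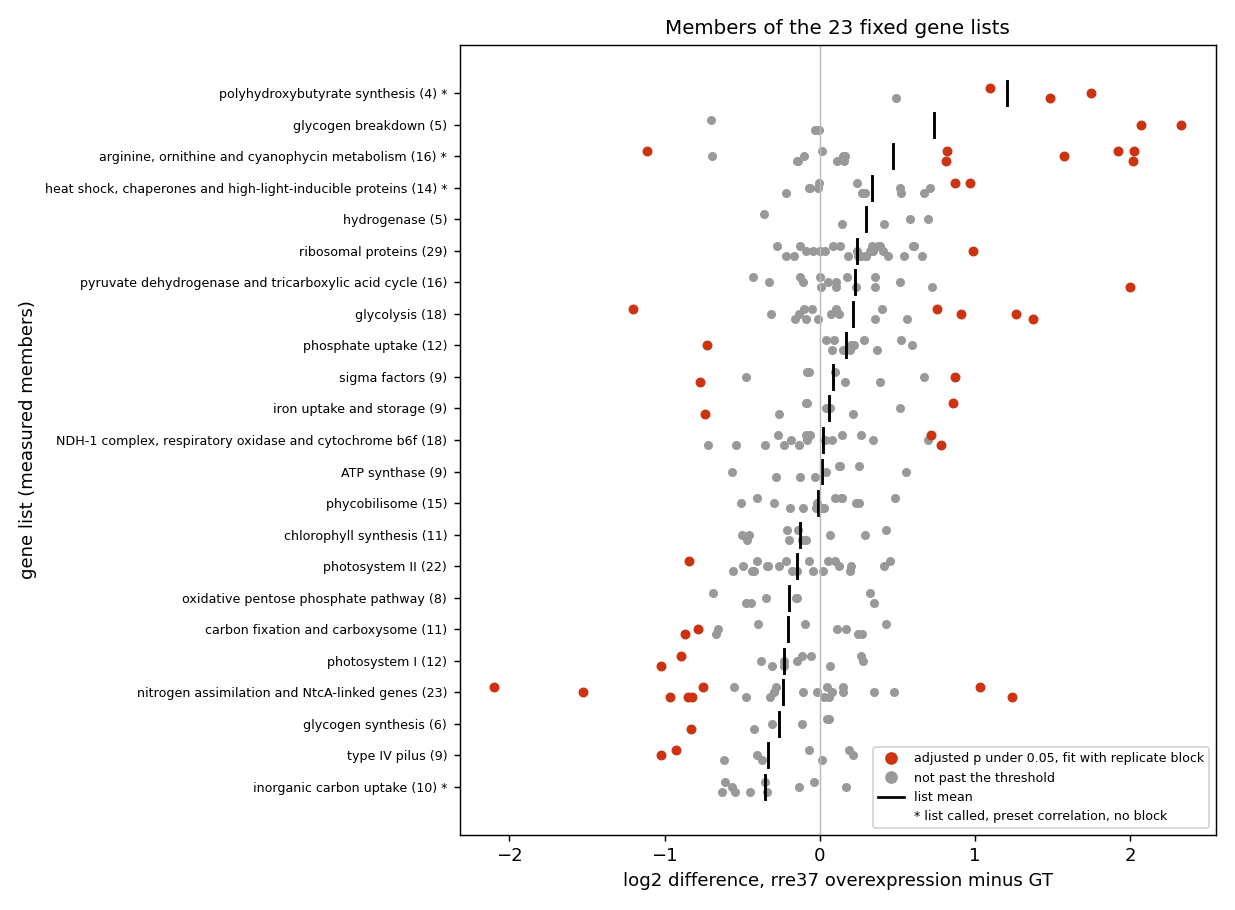
Log2 difference between the strains (horizontal axis, rre37 overexpression minus GT) of each measured member of the 23 gene lists, ordered by the list mean (black bar). Red members passed the threshold in the paired fit, and the means run from -0.35 for inorganic carbon uptake to 1.21 for polyhydroxybutyrate synthesis.

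The 3 loci often used as insertion sites in this organism were examined. The slr2031 gene was 5.07-fold higher in the overexpression strain (7.59 ± 0.156 in GT and 9.93 ± 0.389 in the overexpression strain, log2 intensity, SD, n = 3 each, limma adjusted p = 0.00642). It was 2.24-fold higher without background correction and 2.33-fold in the series table, with adjusted p = 0.00840 and 0.0129. The slr2030 gene had a log2 difference of 0.26 (SE 0.412, adjusted p = 0.891) and slr0168 one of 0.077 (SE 0.246, adjusted p = 0.949). Where the overexpression construct lies is not given in the sources used here.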

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

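All alternatives were fixed before the data were examined, except each spot alone, the paired fit without each pair, and the 2 changed gene lists. Neither rre37, the other 21 called genes that were followed, nor the 4 called lists changed direction under any of them, while some lists that were not called changed sign. The log2 difference of rre37 stayed past the threshold in all 21 alternatives and ran from 4.07 (series table) to 5.25 (first spot alone). The 25 calls became 285 with the replicate block and 308 with the replicate block and loess within pairs, and both included the same 25. They became 16 with an offset of 16, 8 with the first spot alone and 1 with the second spot alone. Leaving out 1 sample gave 1 to 21 calls, with 11 without GT replicate 1, 15 without overexpression replicate 2, 1 without GT replicate 3 and 4 without overexpression replicate 3. The paired fit without pair 1, 2 or 3 gave 288, 205 and 244, and each kept all 25. Its p-values may be too small, as the spread is shared almost wholly between genes. An adjusted p under 0.1 gave 30. The share of called genes that were higher was 72.0%, against 58.3% without background correction, 81.2% with an offset of 16, 61.5% in the series table, 43.2% with the replicate block and 45.5% with the replicate block and loess within pairs. The median log2 difference of all genes was 0.12 in the series table and -0.09 after median scaling, against 0.0012. Of the 23 lists, 4 were called, against 2 with an offset of 16, 7 in the series table (2 of them among the 4), 0 by camera with an estimated correlation, 0 by fry (which tests a list by itself) and 2 to 6 without 1 sample (2 without GT replicate 3 or overexpression replicate 2). The polyhydroxybutyrate list kept its call in 24 of 26 alternatives and the arginine list in 22 (adjusted p = 0.00276 with sll1077 in place of slr1077). These 26 include the 2 changed lists, which leave the polyhydroxybutyrate genes as they were, and the paired fits without 1 pair. Both lists lost the call where no preset correlation was used. Their adjusted p was 0.495 and 0.520 by camera with an estimated correlation, and 0.118 and 0.1455 by fry. The inorganic carbon and heat shock lists each kept theirs in 15, and the ribosomal list, not called, was called in 10. The block over all 3 pairs changed no other list's call. Taking the median of 2 spots equals their mean and was not run. The cause of these shifts was not tested. Fewer samples enter a fit that leaves 1 out, and without pairing its same-numbered partner then stays unmatched. The phycobilisome mean was 0.19 without GT replicate 1 and -0.28 without overexpression replicate 1, and -0.24 and 0.24 for replicate 2. It was 0.022 and 0.011 for replicate 3, and -0.083 to 0.043 in the paired fit without 1 pair. For replicates 1 and 2 the mean of this list thus moved with the unmatched partner. Dim genes are limited by the pedestal, since the median spot was 1.97 to 3.08 times the lowest of its sample.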

Other observations

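The tests on shared operons, on NtcA and on sigE were chosen after the gene values were seen, and the other tests before. Of 24 operons, 16 had differences of 1 sign in all their genes and 8 had mixed signs. The 5 carboxysome genes ccmK2, ccmK1, ccmL, ccmM and ccmN all had negative log2 differences, from -0.87 to -0.40 with a mean of -0.68. The 4 pilus genes pilM, pilN, pilO and pilQ had a mean of -0.66, and psaA and psaB one of -0.70. Mixed signs were found among others in the ATP synthase operon (-0.56 to 0.56, 5 of 7 positive), the hydrogenase operon (-0.36 to 0.70) and an NDH-1 operon (-0.54 to 0.15, 2 of 4 positive). The 3 oxidase genes ctaC, ctaD and ctaE lay between 0.70 and 0.78. The 6 genes of a phosphate uptake cluster had a mean of 0.35, and 6 of them were positive, against 5 after median scaling. The directions of the carboxysome, pilus, psa and oxidase genes held after median scaling, after cyclic loess and in the series table. Of the 4 genes of the inducible carbon uptake complex (the operon of ndhF3), none was positive, against 2 in the series table.

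The 25 called genes could carry a dye effect, since no dyes were swapped. A dye effect that depends on the signal level is removed by loess within same-numbered pairs, and all 25 kept their direction and an adjusted p under 0.05 after it. That fit was also paired, and pairing without loess kept all 25 too, so the adjusted p decides little. Sizes changed little, with 2.24 after loess against 2.34 for slr2031 and -1.47 against -1.60 for slr2057. Cyclic loess without pairing kept 24 of the 25 calls. The 25 were called after quantile normalisation, which already evens out much of a dye trend with signal level, so keeping them was likely beforehand. These values argue only against a level-dependent dye effect left after that normalisation as the whole cause. Over 97 genes in 24 operons, the intraclass correlation of the log2 differences was 0.710, against -0.155 to 0.183 in the central 95% of 10000 random assignments (permutation p = 1e-04, the smallest they can give). This argues against single-probe effects as the source of the differences in these operons as a set. It leaves them open for genes outside operons, and effects of spot position, which is not given in the sources used here, stay open too.

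Of the 10 splits of the 6 samples, 1, the real one, gave 25 calls and the highest other gave 2, but 10 splits are too few for a share under 0.05. For the gene lists 4 of the 10 splits gave 4 or more calls, and the highest other gave 7. The 6 splits that kept 2 of the 3 pairs together gave 7, 6, 5, 1, 1 and 1 lists. Among the 4 splits that part all pairs, the real one called 285 genes and 5 lists in the paired fit, and the other 3 called 0. These 4 splits are also too few for a share under 0.05. The real split is the split by dye as well, so a dye effect would set it apart in the same way.

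Regulators with known targets were weighed as hypotheses for the sugar catabolic and nitrogen genes. A rise of sigE transcript was not seen, as the upper 95% bound of its log2 difference in the paired fit was -0.0464. This goes against such a rise as the source of the higher glgP, malQ and gap1. A dye effect on the sigE probe cannot be separated from a strain effect, and the activity of its protein was not measured, so both stay open. Lower activity of NtcA, which activates the nrt genes and represses gifA and gifB, would raise both gif genes. The higher of their 2 upper bounds was 0.826, that of gifA (ssl1911), whose interval spans 0, while gifB (sll1515) was lower by 2.10 on the log2 scale. The interval of gifA leaves this explanation open, and gifB goes against it. A direct effect of the excess regulator stays open and was not tested.

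The rise of slr2031 could come from a change that raises it together with slr2030. The upper 95% bound of the paired log2 difference of slr2030 was 0.706, against 2.34 for slr2031. It was 0.340 against 1.16 without background correction and 0.538 against 1.22 in the series table, and the first 2 of these 3 comparisons met the bound set beforehand, which goes against a joint rise. That bound ignored the floor, since slr2030 lay at the 11th percentile of all GT levels, where a rise from below the floor can be missed, although the rise of slr2031 was seen from the 21st. A joint rise, a change confined to slr2031, the position of the construct, and a dye effect of this single probe stay open.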
